A study of Homo sapiens with 2 samples.

How the data were processed

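One array per cell line was hybridised with Cy3-labelled cDNA from total RNA, on a 1-colour CapitalBio human lncRNA design printed by Agilent. MCF-7 and MDA-MB-231 each had 1 array, so the 2 groups have no replicates and no test across arrays was made. The groups were taken from the labels. The scanner files hold spot intensities that the authors obtained with Agilent Feature Extraction 11.5.1.1, per the file headers, with background subtraction and spatial detrending and no scaling between arrays. The deposited expression table holds log2 values that the authors had normalised. Against the scanner signals each of its columns equalled its own array's log2 signal shifted by a constant (r = 1.0 across probes, 100% of the 73517 probes kept below within a tolerance of 0.1). Over all its 75217 rows the column medians were −2.50 and −2.40. Scale and centring of that table were thus known, and the direction was taken from the column names. The grid is based on hg19, per the file headers.

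Each array held 180880 spots, of which 175906 were not controls and belonged to 75149 probes. Control spots were removed, and so were outlier spots, 3.40% for MCF-7 and 2.58% for MDA-MB-231. Outlier flags fell on 25.6% and 25.4% of the brightest 5% of spots and on 0.980% and 0.955% of the dimmer ones below the median. The 1632 probes with all spots flagged on either array were left out, which left 73517. The value of a probe was the mean log2 processed signal over its remaining spots minus the array's 75th percentile. Standard errors from replicate spots used the spot SD pooled over probes in each of 20 bins of signal per array. They combine both arrays, take account of the probe's number of spots and are not measured on the probe alone. The 600 negative control spots had medians of 2.52 and 2.16 scanner units. A probe was called well above background where more than 50% of its spots carried that flag. Differences are MDA-MB-231 minus MCF-7. The number of arrays limits the precision.

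Gene symbols came from the deposited table and were updated through RefSeq gene tables of assembly GRCh38.p14, from which no coordinates are given because its build differs from that of the grid. Of 34235 catalogue probes, 30934 had a symbol and 3301 did not. RefSeq matched 28914 probes by Entrez identifier and 32 by accession, 5289 were not matched, and 2526 symbols were updated. This gave 21419 genes, 18093 coding, 2247 lncRNA and 1079 other. Custom lncRNA probes had no symbol in the files and were reported by identifier. A gene was represented by its probe with the highest mean normalised signal, chosen without regard to the difference. Where a gene was above background on 1 array, printed folds and counts of list members beyond 2-fold use lower bounds, which hold for the reported background correction only. Counts of genes and probes, medians and correlations use measured differences unless bounds are stated.

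Genes were named by a rule set before the data were examined. It took the 10 lncRNAs and 10 coding genes with the largest difference in each direction among those above background on both arrays with probes of 1 sign, and the 5 in each direction with the largest lower bound among those above background on 1 array. It added up to 4 members of each of the 22 fixed lists beyond 2-fold, ESR1, GATA3, CDH1, VIM, EGFR, ERBB2, HOTAIR, MALAT1, NEAT1 and H19, and at most 2 unnamed probes per direction. FOXA1, KRT18, HLA-E, HLA-DRB1, the antisense pairs and the second probes were chosen after their values were seen. The lists were luminal transcription factors, oestrogen-responsive genes, epithelial adhesion, mesenchymal genes, basal markers, matrix and proteases, inflammatory genes, interferon-stimulated genes, HLA and antigen presentation, p53 targets, cell cycle, receptor tyrosine kinases, hypoxia and glycolysis, housekeeping genes, haematopoietic, endothelial and fibroblast markers, cancer lncRNAs, oestrogen receptor lncRNAs, snoRNA host lncRNAs, HOX cluster lncRNAs and HOX genes. A list's median was placed among 10000 random lists of the same size, drawn from 20 bins of mean signal. Pairs of a lncRNA and a coding gene were made from their names, and their correlation was set beside 10000 random pairings.

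Alternatives were quantile normalisation, the percentile over detected probes, normexp background correction with an offset of 50, loess removal of an intensity trend with a span of 0.3, housekeeping centring, the deposited table, 2 other filters on dim probes, the median over probes, a 4-fold threshold and other detection rules. Normexp used the median spot signal, because the mean spot signal is not in the files used here. The representative probe of a gene was chosen again under each normalisation. Keeping outlier spots, centring on the E1A control probes and counting at lower bounds were added after the data had been seen. Shares have Wilson 95% intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. The steps were tested on simulated data for the difference between the lines with 15198 genes. They recovered 98.0% of 100 genes set at a log2 difference of 1.5 and 100% of 100 genes set at 3, and called 0 of 14998 unchanged genes. Both simulated arrays were made from the MCF-7 array and its detection flags, with noise between replicate spots only. The changed genes were bright coding genes. These values check the steps and give no error rate for the real arrays, where probes of the same gene had an SD of 0.75. Of 200 random lists 6.00% fell outside the central 95% interval, and over 600 simulated pairs r was 0.527 where 0.5 had been set.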

Results

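Total RNA from 2 human breast cancer cell lines was profiled, with 1 array per line and no replicates, so sizes and counts are given without p-values. MCF-7 is an oestrogen receptor positive luminal line, and MDA-MB-231 is a triple-negative line with mesenchymal features. The arrays measured long non-coding RNAs (lncRNAs), coding transcripts and small RNAs, and the labels give the lncRNA profile of each line as the purpose. Both arrays lay on the same slide and were scanned together, with no saturated spot. The MCF-7 array was brighter, with a 75th percentile of signal of 313.5 against 119.9 scanner units, and 70.2% against 61.5% of spots well above background. After scaling, the correlation between the lines across 41724 probes above background on both arrays was r = 0.849, which is across probes and not across replicates. Replicate spots of a probe had a standard deviation (SD) of 0.23 on the log2 scale for MCF-7 and 0.25 for MDA-MB-231. Different probes of the same gene had an SD of 0.75 in the log2 difference between the lines, the only spread against which single differences can be set. Among 4009 genes with several probes above background on both arrays, the probes shared the sign of the difference in 67.2%, and in 85.8% of the 1193 genes that were at least 2-fold apart.

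The first comparison concerns how many lncRNA and coding probes gave signal in each line. Of 37694 custom lncRNA probes, 60.6% were well above background in MCF-7 (Wilson 95% interval 60.1 to 61.1) and 50.3% in MDA-MB-231 (49.8 to 50.8). Catalogue probes for named lncRNAs gave 57.3% (55.5 to 59.1) and 47.2% (45.4 to 49.1). Protein-coding probes were detected more often, at 81.9% (81.4 to 82.4) in MCF-7 and 74.7% (74.2 to 75.2) in MDA-MB-231. Small nucleolar RNA (snoRNA) probes, for the guides of rRNA modification, gave 82.6% (77.9 to 86.5) and 79.6% (74.7 to 83.8). Among the snoRNA probes above background in both lines, 72 were at least 2-fold higher in MDA-MB-231 and 21 in MCF-7, with a median log2 difference of 0.53. These counts rested on the scaling, with 44 and 31 and a median of 0.12 with housekeeping genes as the zero, and 33 and 41 and a median of −0.064 with the E1A control probes as the zero. The intervals cover the number of probes only, and the 2 arrays differed in brightness. The gap for custom lncRNA probes, 10.4 percentage points here, was 4.17 points by the scanner's positive and significant flag (77.3% against 73.2%). It was 3.03 points above the 95th percentile of negative controls (83.0% against 80.0%).

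Among 1416 named lncRNA genes above background in either line, 287 were at least 2-fold higher in MDA-MB-231 and 285 in MCF-7. Among 15627 coding genes the counts were 2799 and 3245, and among 24174 custom lncRNA probes they were 4848 and 4670. These counts use measured differences, including those of probes too dim to be called on 1 array. With such probes at their lower bounds the counts were 285 and 236 lncRNA genes, 2787 and 3074 coding genes, and 4803 and 3747 custom probes. The share beyond 2-fold was 40.4% for named lncRNA genes, 38.7% for coding genes and 39.4% for custom lncRNA probes. Of the genes above background in a single line, 314 lncRNA and 1502 coding genes were seen in MCF-7 only, and 74 lncRNA and 434 coding genes in MDA-MB-231 only. By their lower bounds, 128 and 821 of the former and 74 and 432 of the latter were at least 2-fold apart. A bound is set against the lowest signal among well-detected probes where the dim probe lies under it. After scaling that level was −5.36 in MCF-7 and −4.30 in MDA-MB-231, more than 2-fold apart. A gene seen in MDA-MB-231 only and dimmer than that level in MCF-7 thus passed 2-fold by construction. Counts and shares at the bounds are therefore not alike in the 2 directions. The balance between the lines rested on the scaling and on the dim probes. MDA-MB-231 held 50.9% of the custom lncRNA probes beyond 2-fold, 50.2% of the lncRNA genes and 46.3% of the coding genes, as measured. At the bounds these shares were 56.2%, 54.7% and 47.6%, and with only probes and genes above background in both lines 64.5%, 66.0% and 51.1%. With housekeeping genes as the zero they were 31.6%, 33.5% and 27.7%. With the E1A control probes as the zero they were 25.2%, 27.5% and 21.4%, and with another background correction (normexp) 79.1%, 77.9% and 48.5%.

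Among lncRNAs above background in both lines, the largest difference towards MDA-MB-231 was that of ARLNC1, an androgen receptor regulated lncRNA described in prostate cancer, at 85.7-fold (log2 difference 6.42, standard error from replicate spots 0.28). Next came lnc-CD2AP-2 at 34.4-fold, LINC02985 at 27.4-fold and MIR3681HG, a microRNA host transcript, at 24.6-fold. CECR7, PGM5P4-AS1, lnc-ZNF674-3, LOC102724434, lnc-FNBP1L-1 and lnc-GLIPR1-3 were between 19.3-fold and 11.2-fold higher. Such sizes depend on the background correction, and under normexp ARLNC1 was 18.4-fold higher and LINC01291 35.1-fold lower. In the other direction, LINC01291 was 39.4-fold lower in MDA-MB-231 than in MCF-7 (log2 difference −5.30, standard error 0.14), lnc-PRR11-1 was 31.1-fold lower and BRINP3-DT 19.7-fold lower. ATXN1-AS1, LINC01087, RNF32-DT, PIK3R5-DT, lnc-KIAA0226-2, lnc-RASSF7-1 and LINC02983 were lower by 18.3-fold to 7.77-fold. Where a transcript was well above background in a single line, the bright value was set against the higher of the dim probe's own signal and the lowest signal among well-detected probes, which gives a lower bound for the reported background correction only. That lowest signal was 7.64 scanner units for MCF-7 and 6.10 for MDA-MB-231, or −5.36 and −4.30 after scaling. The level at which 50% of probes were flagged was higher, 13.7 and 11.9 units, and would give smaller bounds where the dim probe lies under it. Under normexp all 45 named or listed genes with a reported bound of at least 2-fold lay below it. Its offset of 50 units exceeds both lowest signals and shrinks such folds almost whatever the data. That outcome is therefore no separate check of the bounds. Each "at least" here holds for the reported background correction and the lowest signals used. Of 124 named or listed genes at least 2-fold apart, 8 no longer were under normexp. Over all genes at least 2-fold apart, 230 of 521 lncRNA genes and 1986 of 5861 coding genes no longer were. Detected in MDA-MB-231 only, lnc-CSAG1-1 was at least 121-fold higher, LOC101448202 at least 104-fold and LOC102723724 at least 74.3-fold, followed by LINC02229 at 68.7-fold or more and CCDST at 68.3-fold or more. Detected in MCF-7 only, IRX4-AS1 was at least 70.1-fold lower in MDA-MB-231, lnc-NCOA3-1 at least 52.7-fold, LINC02506 at least 33.9-fold, lnc-PRICKLE2-3 at least 33.4-fold and GATA3-AS1 at least 32.3-fold.

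**Figure D1:**
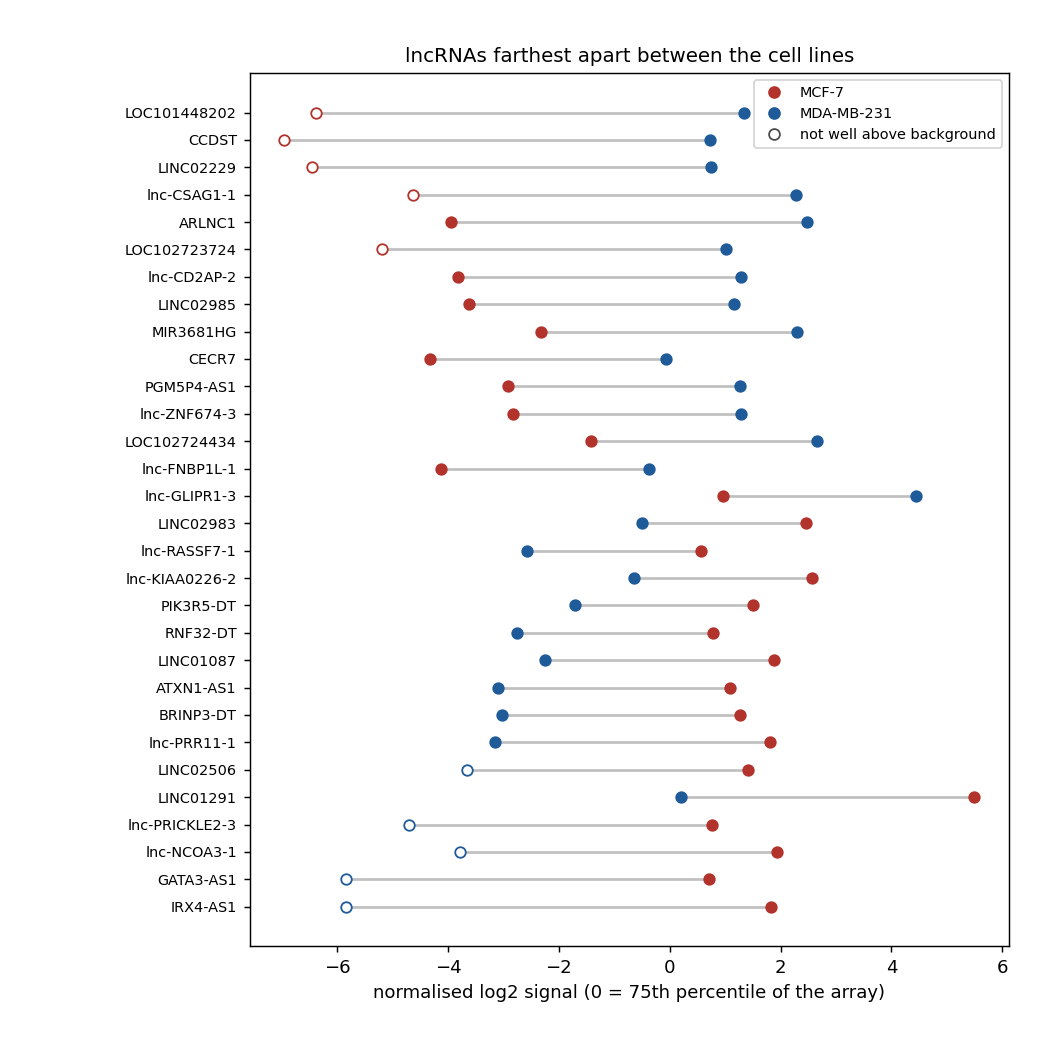
Normalised log2 signal (0 is the array's 75th percentile) of the 30 lncRNAs named by the rule, with a red point for MCF-7 and a blue point for MDA-MB-231, open where not well above background, and a grey line joining them. The points of ARLNC1 lie at −3.94 and 2.48 and those of LINC01291 at 5.50 and 0.20.

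Among coding genes above background in both lines, FLNC, which encodes an actin cross-linking filamin, had the largest difference towards MDA-MB-231, at 1030.3-fold higher (log2 difference 10.01, standard error from replicate spots 0.23). The intermediate filament gene VIM was 989-fold higher, the Rho inhibitor gene ARHGDIB 537-fold, TM4SF1 445-fold and the actin-binding NEXN 379-fold. Under normexp FLNC was 329-fold and VIM 408-fold higher. FXYD5, GPX1, NT5E, EMP1 and RAC2 were between 349.7-fold and 254-fold higher. In the other direction, among genes detected in both lines, the histone gene H4C5 was 333-fold lower in MDA-MB-231, the microtubule-end protein gene CAMSAP3 173-fold, and the developmental transcription factor genes ASCL1 and TBX2 168-fold and 134-fold. PCP4, PPL, ELF3, PYCARD, STARD10 and GATA3 were lower by 118-fold to 80.8-fold. Detected in MDA-MB-231 only, the cancer-testis antigen gene XAGE1A was at least 2415-fold higher, SLC43A3 at least 2369.8-fold, ANKRD1 at least 1469-fold, COL13A1 at least 1238-fold and CAVIN3 at least 1237-fold. Detected in MCF-7 only, SPTSSB, of sphingolipid synthesis, was at least 1074-fold lower, H2BC7 at least 808-fold, TPD52L1 at least 665-fold, and the epithelial regulators GRHL2 and ESRP1 at least 434-fold and 296-fold.

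Oestrogen receptor and luminal genes were lower in MDA-MB-231 as a group. Of 15 measured members of the luminal list, 14 were at least 2-fold lower and none higher, with a median log2 difference of −4.31 (19.9-fold). ELF3 was 94.1-fold lower, the luminal regulator GATA3 80.8-fold, the progesterone receptor gene PGR at least 75.8-fold, and the oestrogen receptor gene ESR1 75.2-fold. The other 2 ESR1 probes were not well above background in MDA-MB-231, with measured log2 differences of −8.96 and −10.55. FOXA1, a pioneer factor of the luminal programme, was the 1 member within 2-fold, at a log2 difference of 0.07. KRT18 was also within 2-fold, at −0.59, with outlier spots kept. Oestrogen-responsive genes had a median of −2.09, with 16 of 23 at least 2-fold lower and 2 higher, or −1.46 with only genes above background in both lines. Under normexp the luminal median was −3.67. STC2 was at least 198-fold lower, GREB1 at least 138-fold and the zinc transporter gene SLC39A6 50.1-fold. Both medians lay below all 10000 random lists of the same size and mean signal, which describes these 2 arrays only. With outlier spots kept, which brought in another probe, the GREB1 value was 64.6-fold.

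Epithelial adhesion genes were also lower in MDA-MB-231 and mesenchymal genes higher. Of 29 epithelial genes, 25 were at least 2-fold lower and 3 higher, with a median of −4.23, or −4.17 with genes seen in a single line at their bounds. The median was −2.66 under normexp and −3.17 with only genes above background in both lines. GRHL2 was at least 434-fold lower, the splicing regulator gene ESRP1 at least 296-fold, the vesicle trafficking gene RAB25 at least 217-fold and the receptor gene ERBB3 at least 94.1-fold. CDH1, which encodes E-cadherin, had every spot marked as an outlier on at least 1 array, and was at least 263-fold lower with those spots kept. Of 33 mesenchymal genes, 24 were at least 2-fold higher and 1 lower, with a median of 2.63 (6.20-fold), 1.89 under normexp and 1.74 with only genes above background in both lines. VIM was 989-fold higher, the receptor kinase gene AXL at least 921-fold, the ectonucleotidase gene NT5E 298-fold and the protease inhibitor gene SERPINE1 at least 118-fold. Under normexp AXL was 93.1-fold and SERPINE1 12.99-fold higher. The epithelial median lay below all random lists and the mesenchymal median above all of them.

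Basal markers, matrix genes and receptor kinases were mixed. Of 14 basal markers, 6 were at least 2-fold higher in MDA-MB-231 and 2 lower, with a median of 0.64 at percentile 95.6 of random lists. EGFR was 20.7-fold higher, LAMC2 8.80-fold and ITGA6 7.54-fold, whereas the P-cadherin gene CDH3 was 27.4-fold lower. A further EGFR probe gave a log2 difference of 7.53 against 4.37 for the brightest one. Matrix, integrin and protease genes had a median of 0.73, with 15 of 32 at least 2-fold higher and 4 lower, above 99.96% of random lists. Genes of the plasminogen activator system led, with PLAU 67.0-fold, PLAT 56.3-fold and PLAUR 43.6-fold higher, beside the integrin gene ITGB3 at least 39.0-fold. Among 30 receptor tyrosine kinases and ligands, 14 were at least 2-fold higher and 11 lower, with a median of 0.80 above 99.98% of random lists. The growth factor gene NRG1 was at least 631-fold higher and PDGFC at least 79.0-fold, while ERBB2 differed by 1.12-fold. With outlier spots kept another NRG1 probe gave 60.1-fold, and with only genes above background in both lines the receptor list lay at percentile 81.1 with a median of 0.21. With the E1A control probes as the zero, the basal, matrix and receptor medians were 0.05, 0.13 and 0.20, so their distance from 0 rested on the scaling. Under normexp the basal list moved to percentile 99.2.

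The medians of the cytokine and antigen presentation lists were higher in MDA-MB-231. Inflammatory genes had a median of 1.45 (1.37 with bounds), with 14 of 26 at least 2-fold higher and 3 lower. The chemokine gene CCL2 was at least 145-fold higher, the growth factor genes CSF1 and CSF2 52.0-fold and at least 11.7-fold, and the cytokine gene IL32 11.2-fold. HLA and antigen presentation genes had a median of 1.22, with 11 of 18 at least 2-fold higher and 2 lower. The peptide transporter gene TAP2 was 28.3-fold higher, the immunoproteasome gene PSMB8 6.47-fold, HLA-B 5.99-fold and HLA-C 4.88-fold. HLA-DRB1, measured only with outlier spots kept, was 7.57-fold lower. Both medians lay above all random lists. Interferon-stimulated genes had a median of 0.71 at percentile 99.6, with 12 of 25 at least 2-fold higher and 2 lower. IFI44 was at least 147-fold higher, BST2 22.2-fold and IFI27 13.97-fold, whereas IFITM1 was 15.9-fold lower. With only genes above background in both lines, the inflammatory list lay at percentile 97.05 with a median of 0.70. With the E1A control probes as the zero the inflammatory, antigen presentation and interferon medians were 0.85, 0.62 and 0.11.

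Genes of p53, growth and metabolism differed less. Of 26 p53 targets, 8 were at least 2-fold lower in MDA-MB-231 and 4 higher, with a median of −0.51 at percentile 1.45. The antiproliferative gene BTG2 was 14.02-fold lower, the stress gene SESN1 at least 4.98-fold and GDF15 4.09-fold, whereas TP53I3 was 3.53-fold higher. Under normexp BTG2 was 5.78-fold lower, SESN1 1.07-fold lower and TP53I3 1.99-fold higher, so the last 2 were within 2-fold. Cell cycle genes had a median of 0.25 at percentile 50.8, with 8 of 26 at least 2-fold higher and 1 lower. CENPF, of the kinetochore, was 3.44-fold higher, the replication gene MCM7 2.98-fold, AURKB 2.56-fold and UBE2C 2.38-fold (1.958-fold under normexp). Hypoxia and glycolysis genes had a median of 0.51 at percentile 94.1, with 7 of 27 at least 2-fold higher. These included the lactate exporter gene SLC16A3 at 10.1-fold, ANKRD37 at 5.90-fold, the glucose transporter gene SLC2A3 at 5.09-fold and VEGFA at 3.57-fold. Housekeeping genes had a median of 0.41 at percentile 70.0, with RPS18 (2.66-fold), ACTB (2.44-fold) and B2M (2.43-fold) the 3 of 25 beyond 2-fold, all higher in MDA-MB-231 (ACTB and B2M within 2-fold under normexp). The cell cycle, hypoxia and housekeeping medians changed sign under some alternatives.

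Some markers of cell types other than breast cancer cells were above background. Of 14 haematopoietic markers on the array 7 were above background in either line, with a median of −0.15 at percentile 37.0, and CD68, a lysosomal protein of macrophages, was 20.1-fold higher in MDA-MB-231. Endothelial markers had a median of 0.44 at percentile 83.3 over 8 of 11 genes. ESAM was 24.5-fold higher, ROBO4 at least 17.0-fold and PECAM1 at least 14.3-fold, while EMCN was at least 10.97-fold lower. Under normexp ESAM was 12.9-fold, ROBO4 4.16-fold and PECAM1 3.05-fold higher, and EMCN was 1.985-fold lower. Fibroblast markers had a median of −0.90 (−0.62 with bounds) at percentile 16.8 over 5 of 12 genes. The collagen gene COL3A1 was at least 74.8-fold lower and COL1A1 at least 3.56-fold, and ACTA2 was 2.71-fold higher. Under normexp COL3A1 was 9.12-fold lower and COL1A1 changed sign, to a log2 difference of 0.013. These 3 medians changed sign under some alternatives.

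**Figure D2:**
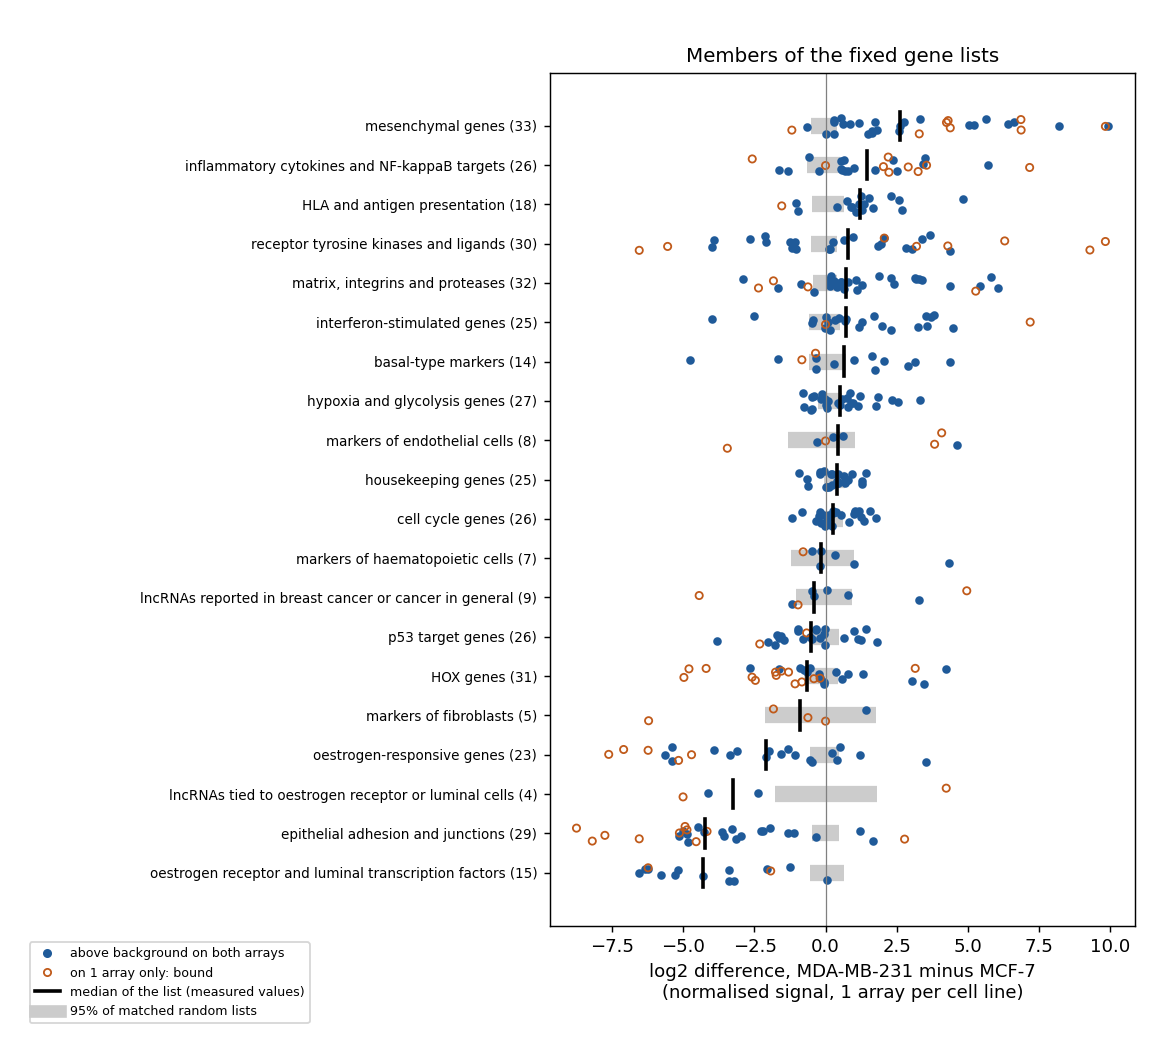
Log2 difference (MDA-MB-231 minus MCF-7) of each measured member of the gene lists, 1 point per gene, with the number of genes in brackets. Blue points are above background on both arrays, open points on a single array (drawn at the bound), black bars are list medians and grey bands hold 95% of matched random lists. The luminal list (median −4.31) and the epithelial list (−4.23) lie on the MCF-7 side and the mesenchymal list (2.63) on the MDA-MB-231 side.

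Fixed lncRNA lists were only partly on the array under a symbol. Of 60 cancer lncRNAs, 11 were on the array and 9 were measured, with a median of −0.40 at percentile 19.1, and 2 were at least 2-fold higher in MDA-MB-231 and 2 lower. LUCAT1 was at least 31.3-fold higher and LINC00472 9.72-fold, whereas HOTAIR, transcribed from the HOXC cluster, was at least 21.8-fold lower and PVT1, next to MYC, 2.25-fold lower. Under normexp LUCAT1 was 4.42-fold higher and HOTAIR 3.85-fold lower. MALAT1, NEAT1 and H19 had no probe under those symbols and were not analysed here. Of 4 measured lncRNAs tied to the oestrogen receptor or luminal cells, 3 were lower in MDA-MB-231, with a median of −3.24 at percentile 0.17. GATA3-AS1 was at least 32.3-fold lower, LINC01087 17.5-fold and ZNF217-AS1 5.13-fold, and LINC00993 was at least 18.98-fold higher. Under normexp GATA3-AS1 was 4.94-fold and ZNF217-AS1 1.964-fold lower, and LINC00993 3.65-fold higher. HOTAIR was the 1 HOX cluster lncRNA on the array of 21 listed, and none of the 23 listed snoRNA host lncRNAs was found by symbol. Of 31 measured HOX genes, which set positional identity, 12 were at least 2-fold lower in MDA-MB-231 and 5 higher, with a median of −0.66 at percentile 4.19. HOXC13, HOXC11 and HOXA5 were at least 31.6-fold, 28.0-fold and 18.4-fold lower, and HOXB3 was 18.8-fold higher. Under normexp these were 5.31-fold, 4.23-fold and 2.34-fold lower and 5.05-fold higher. The medians of the cancer lncRNA and HOX gene lists changed sign under some alternatives.

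The differences of antisense lncRNAs and their coding partners were correlated beyond those of random pairs. GATA3-AS1 and GATA3 were both lower in MDA-MB-231, at least 32.3-fold and 80.8-fold. ID2-AS1 and ID2, an inhibitor of basic helix-loop-helix factors, were lower by at least 12.4-fold and by 39.8-fold, and IRX4-AS1 and IRX4 by at least 70.1-fold and by 43.2-fold. EGFR-AS1 was at least 27.3-fold higher beside EGFR at 20.7-fold, SPRY4-AS1 was 9.13-fold higher beside SPRY4 at 43.8-fold, and VIM-AS1 was 3.92-fold higher beside VIM at 989-fold. Under normexp ID2-AS1 was 2.03-fold and IRX4-AS1 9.97-fold lower, while EGFR-AS1 was 4.42-fold and EGFR 66.0-fold higher. The brightest probe was chosen again there, so the EGFR value may come from another probe. In the reported correction the 2 EGFR probes above background in both lines had log2 differences of 7.53 and 4.37, the latter the reported one. FGD5-AS1 went the other way from its partner, 2.05-fold lower beside FGD5 at 2.07-fold higher. Larger departures, as measured log2 differences, were TIAM1-AS1 (−3.94) beside TIAM1 (0.61) and LSAMP-AS1 (−1.34) beside LSAMP (4.57). TM4SF1-AS1 differed little (0.13) beside TM4SF1 (8.80). Across 131 antisense pairs the correlation of the log2 differences was r = 0.439 (Spearman's rho 0.362), and the highest value in 10000 random pairings was 0.321. Over all 648 pairs of a lncRNA and its named coding gene it was 0.232 (rho 0.193) against a highest random value of 0.147, and 55.4% of pairs shared a direction, below the highest random share of 57.6% (random median 50.2%). Of the antisense pairs 58.8% shared a direction, also below the highest random share of 66.4%. Divergent pairs (46) gave r = 0.263 and neighbour pairs (468) gave 0.146, both below their highest random values of 0.588 and 0.168. The central 95% of random values ended at 0.301 and 0.0918, so divergent pairs lay inside it and neighbour pairs above it. With only genes above background in both lines r was 0.444 over 80 antisense pairs (highest random value 0.411) and 0.251 over all 398 pairs (0.180). Of 33 antisense pairs with both genes beyond 2-fold, 26 shared a direction. Genes are not independent replicates, so these correlations carry no p-value.

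**Figure D3:**
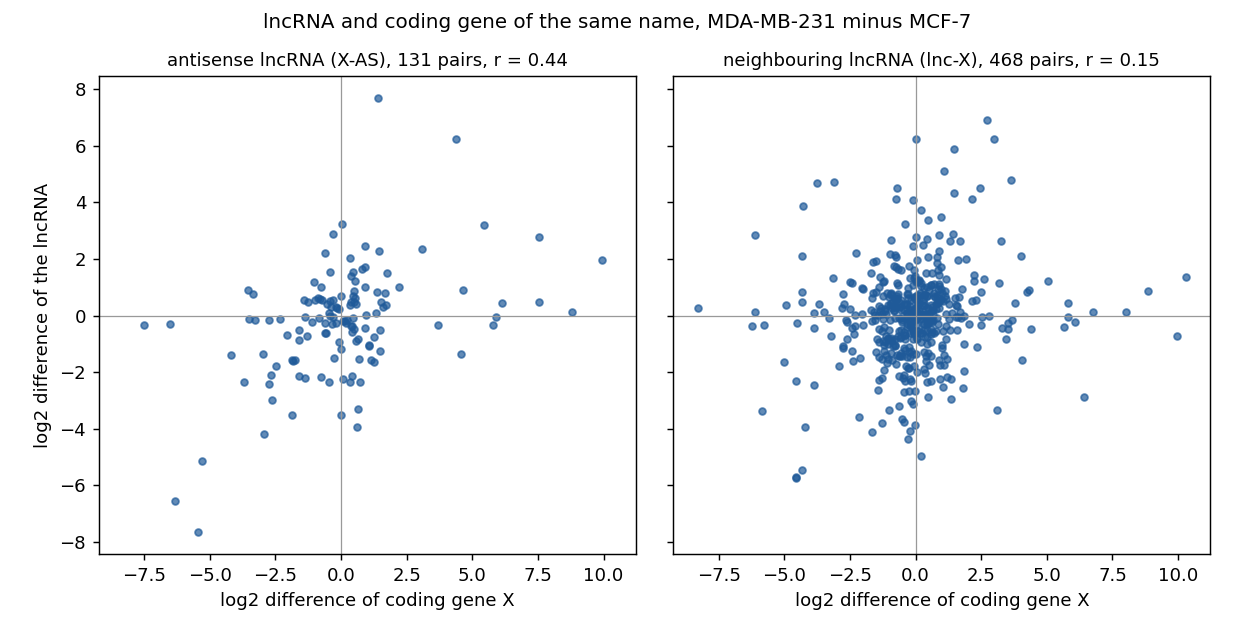
Log2 difference (MDA-MB-231 minus MCF-7) of each lncRNA on the vertical axis and of its paired coding gene on the horizontal axis, 1 point per pair, as measured. The left panel holds 131 antisense pairs (r = 0.439) and the right panel 468 neighbour pairs (r = 0.146).

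Custom lncRNA probes carry only probe identifiers in the files and are named by these. Probe p29587 was higher in MDA-MB-231 by a log2 difference of 7.92 (standard error from replicate spots 0.22), and p2550 by 7.13 (0.36). Probe p33591 had a log2 difference of −8.23 (0.22) and p33840 one of −7.65 (0.26), both higher in MCF-7. Among the 17636 custom probes above background in both lines, 3489 were at least 2-fold higher in MDA-MB-231 and 1920 in MCF-7, a split of 64.5% where the larger set gave 50.9%.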

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

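No test in this part was chosen after its result was seen. A signal in control probes that enter no comparison was noted. Of 12 probes for ERCC spike-in transcripts, 3 had a median signal above the 95th percentile of the negative control spots on both arrays. Their signals were 455.7, 200.2 and 12.1 scanner units in MCF-7 and 225.6, 73.5 and 5.20 in MDA-MB-231. The labels do not say whether such transcripts were added, and no biological explanation was tested.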

How the results depend on the processing

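Keeping outlier spots, centring on the E1A probes and counting at lower bounds were chosen after the data had been seen, and the others before. Counts follow the order custom lncRNA probes, lncRNA genes and coding genes, and list values are medians minus the median of matched random lists. No count or list crossed its threshold under quantile normalisation, loess, the other percentile or the deposited table, and no count at lower bounds. The threshold of a count was a set ratio to the reported count, so smaller changes are not listed. Lists were judged against random lists and not by their raw medians. Under quantile normalisation the raw hypoxia median went from 0.51 to −0.04 and the housekeeping median from 0.41 to −0.05. Under normexp, genes higher in MCF-7 numbered 975, 65 and 2150, and the lists were luminal −3.57, epithelial −2.58, mesenchymal 1.78, inflammatory 0.63 and basal 0.53, the last now outside the random interval. Its added offset is a larger share of the signal on the dimmer array. COL1A1 had a log2 difference of 0.013 there, the 1 of 1330 values for 125 named or listed genes to reverse by more than the spread between probes, and 120 others moved. ERBB2, near 0, crossed 0 under normexp and both centrings. Normexp alone gave 98 of the 120, so 26 of the 125 genes stayed the same under it. Genes higher in MDA-MB-231 numbered 3078, 191 and 1806 with housekeeping centring. With E1A centring they numbered 2604, 166 and 1519 and those higher in MCF-7 7748, 438 and 5577. Both centrings move all values by a constant. With only genes above background on both arrays, 1920 custom probes and 108 lncRNA genes were higher in MCF-7 (64.5% and 66.0% of those beyond 2-fold were higher in MDA-MB-231). The lists then were oestrogen-responsive −1.48, epithelial −3.24, mesenchymal 1.70 and basal 1.18 (now outside), while inflammatory 0.51 and receptor kinases 0.22 fell inside the random interval. Without a filter 13509, 802 and 4315 were higher in MDA-MB-231 (73.8%, 72.6% and 56.8%). The negative control probe had a log2 difference of 1.16 after scaling, so background signal alone can pass 2-fold in that direction. The median over probes gave epithelial −3.62 and HOX genes −0.91 (now outside), and all spots kept gave epithelial −3.67. At 4-fold, 1862, 127 and 1121 were higher in MDA-MB-231 and 1824, 126 and 1396 in MCF-7. By the positive and significant flag 77.3% and 73.2% of custom and 89.1% and 85.7% of coding probes were detected in MCF-7 and MDA-MB-231, with 2126 custom probes in MDA-MB-231 only and 1660 coding probes in MCF-7 only. Above the negative control 95th percentile these were 83.0%, 80.0%, 92.3% and 90.2%, with 3347 custom probes in MCF-7 only, 2208 in MDA-MB-231 only and 1317 coding probes in MCF-7 only. Beyond the constructions named, the cause was not tested. The median over all probes shifted against the reported scaling by −0.36 (quantile), −0.43 (loess), 0.31 (normexp), −0.41 (housekeeping) and −0.59 (E1A). Of 20 list medians, 12 kept their sign under all alternatives that gave a value and 8 did not: HOX genes, cell cycle, housekeeping, hypoxia, cancer lncRNAs, endothelial, fibroblast and haematopoietic. Detection flags of the deposited table were not run because it has none. No paired analysis was possible because each line has 1 array. Signal over background limits the dim probes, with 61.5% of MDA-MB-231 spots well above it.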

Other observations

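The gene families in this part were chosen after the differences between the lines had been seen. A scan of 279 families of at least 8 genes with the same start of their symbol placed 7 above the 99.5th and 5 below the 0.5th percentile of 2000 random lists, metallothioneins and ZNF genes among them. The largest of the 7 was the olfactory receptor (OR) family of 162 genes, with a median of 0.56 and 53 higher against 14 lower. The negative control probe had a log2 difference of 1.16 after scaling, so signal near background leaned to MDA-MB-231 without expression. The cancer-testis, histone, ribosomal protein and clustered protocadherin sets were assembled separately by symbol. In the scan the RPL genes lay at percentile 99.75. Symbols starting with RPS, which also take in RPS6K kinase genes, lay at percentile 80.5. The tests of explanations were set before their own results were seen, except that leaving out 1 antisense pair was added afterwards. For the sets described below, each direction of the median held under all 6 scalings compared. The OR family was not followed over these scalings. Its median of 0.56 is smaller than the 0.594 that centring on the E1A control probes takes off. Metallothioneins, which bind zinc and copper, had a median log2 difference of 3.19 over 8 genes, from 2.59 to 3.20 over scalings. MT1M was at least 485.5-fold higher in MDA-MB-231, MT1E 30.02-fold, MT1X 10.3-fold, MT1B 9.57-fold and MT1A 8.65-fold, whereas MT1F (−0.18), MT3 (−0.11) and MT4 (−0.05) differed little. Cancer-testis antigen genes had a median of 1.21 over 26 genes, with 14 at least 2-fold higher and 1 lower and a range over scalings from 0.61 to 1.22. MAGEA12 was at least 302-fold higher, MAGEA1 at least 168-fold and MAGEA6 23.6-fold. Bounds in this part hold for the reported background correction only, and under normexp MT1M was 56.1-fold and MAGEA12 23.3-fold higher.

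Histone genes had a median of 1.0 over 50 genes, with 25 at least 2-fold higher in MDA-MB-231 and 9 lower, and a range over scalings from 0.26 to 1.01. The exceptions were large, with H2BC7 at least 808-fold lower, H4C5 333-fold, H2AC16 at least 85.8-fold and H2BC21 at least 49.8-fold. Cytosolic ribosomal protein genes had a median of 0.91 over 61 genes, with 27 at least 2-fold higher and 1 lower and a range over scalings from 0.26 to 0.92. Zinc finger ZNF genes leaned to MCF-7, with a median of −0.46 (−0.45 with bounds) over 458 genes and 131 at least 2-fold lower against 32 higher, and a range over scalings from −1.05 to −0.25. With outlier spots kept, further bright genes could be given, among them TFF1 at 18.2-fold lower, AGR2 83.9-fold lower and XBP1 12.8-fold lower in MDA-MB-231, and ANXA1 289-fold, LDHB 79.7-fold and CCN1 71.8-fold higher. Not all followed their list. The luminal gene KRT18 was within 2-fold (1.51-fold lower), and the antigen presentation genes HLA-E and HLA-DRB1 were 1.62-fold and 7.57-fold lower.

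All 38 measured genes of the clustered protocadherins, neural adhesion proteins, were lower in MDA-MB-231 in the reported scaling, 34 of them at least 2-fold, with a median of −3.21 (−2.54 with genes seen in a single line at their bounds) and a range over scalings from −3.81 to −1.09. Of the 38 genes, 23 were above background on 1 array only and entered the set through that array. Their shared direction is thus partly set by the filter. PCDHGB4 was at least 57.2-fold lower, PCDHGA9 28.2-fold and PCDHB2 18.7-fold. The tables argue against the loss of a region larger than the cluster, since the 30 coding genes flanking it had a median of 0.317, inside the range of random runs (−0.87 to 0.837). A shared transcript read by all probes is left open. The SD between 15 cluster genes above background on both arrays was 1.32 (95% interval 0.932 to 1.57) against 0.746 between probes of the same gene. An interval above the latter had been set as the value against it. That comparison cannot decide, because the 0.746 pools genes of all sizes of difference. Probes of a strongly changed gene can differ more, as 2 EGFR probes above background on both arrays did, at 7.53 and 4.37. A loss confined to the cluster, partial cross-hybridisation and a difference in the regulation of the cluster between the lines may each still apply, and were not tested.

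Antisense lncRNAs and their coding partners differed together (r = 0.439, 95% interval 0.29 to 0.568). Differences shared by a whole chromosome region are argued against as the whole cause, since the same lncRNAs and the coding genes adjacent to the partner gave r = 0.128 (−0.0451 to 0.293) over 261 pairs. That interval was computed with the number of pairs divided by 2. All intervals here treat gene pairs as independent, which they are not, so they may be too narrow and the argument is weaker than they show. Overlap of the transcribed spans is left open. The 23 pairs without overlap gave r = 0.526 (0.145 to 0.771) beside 0.43 over 108 overlapping pairs, and an interval above 0 had been set as the value against overlap. That bound was too weak, because without the ID2-AS1 pair r was 0.362 (−0.0706 to 0.680). Shared local regulation in each line may account for it and remains a hypothesis that was not tested, since 2 arrays give no other measure of it.

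Fewer custom lncRNA probes were above background in MDA-MB-231, by 10.4 percentage points. By the positive and significant flag the gap was 4.17 points, and above the 95th percentile of negative controls 3.03 points. With the detection levels matched by the mean brightness gap of the E1A control probes the gap was 4.462 points (54.3% against 49.8%), and it ran from −0.119 to 9.79 over single E1A probes. The dimmer MDA-MB-231 array and a lower number of expressed lncRNAs cannot be told apart, because the control probes disagree and the labels do not say whether the controls were added equally.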
